A study of Mus musculus with 2 samples.

How the data were processed

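H3K4me3 was measured by chromatin immunoprecipitation and sequencing in forebrain of mouse embryos of 14.5 days, in 2 biological replicates of 1 group. Per the labels, replicate 1 was made from a pool of 24 embryos and replicate 2 from a pool of 34, of both sexes, with library fragments of 300 to 500 bp. Replicate numbers were taken from the labels. The data are 4 peak lists on the mouse assembly mm10, which has the coordinates of GRCm38. Per the text deposited beside the files, each replicate's list was derived from that replicate's filtered alignments and a control file of its own, a 3rd list from the alignments of both replicates together with their controls, and the replicated list from those 3 lists. The aligner, the peak caller, its thresholds and the overlap rule of the replicated list are not given in the sources used here.

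Each peak has a start, an end and a summit in the deposited lists. It also has the authors' display score, an integer with a top of 1000, which was not used in any test. The signal of a peak is the enrichment value that the authors' peak caller gave, on a scale that is not stated, and the -log10 p and q values deposited with each peak come from the same caller. Signal was used only to rank or select peaks within a list and never compared between lists. The lowest -log10 p was 2.01 in replicate 1 and 2.03 in replicate 2, and the lowest -log10 q was 0.155 and 0.154, so the deposited lists include weak peaks. Read totals are not in the peak lists, so depth is unknown. A weak or narrow domain may be missed in a shallower library, and the number of peaks of one replicate cannot be set against that of the other as a difference in biology. On assembled chromosomes, 21123 of 21123 replicated peaks were identical in position to a peak of the list of both replicates together, so the replicated list is a selection from it. Of these, 20326 overlapped a peak in each replicate under the overlap rule used here.

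Coordinates were read on GRCm38 with the GENCODE M21 annotation. All peaks ended within the chromosome lengths of this assembly. Peaks on unplaced scaffolds, 22 in replicate 1, 14 in replicate 2 and 12 in the replicated list, were left out of all comparisons. The replicated list was used for the main results, and each replicate's own list was analysed in the same way to give the spread between replicates. Values over replicates are means with the SD (n = 2), which measures the spread of these pools. No test between groups was possible with 1 group. The tests compare gene lists with other genes or with random sets, and their p values describe genes in this tissue. Genes in clusters and genes that share a domain are not independent, which makes such p values too small.

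Peaks were called shared when the overlap reached 50% of the length of either peak, and the share was set against 100 random placements of the same peaks on their own chromosomes outside assembly gaps. A gene was called marked when a peak lay within 1000 bp of the 5' end of any of its protein-coding transcripts (21853 genes, 54361 5' ends). Peaks were classed in the order protein-coding promoter, other promoter, exon, intron and intergenic. Distal peaks lay over 5000 bp from every annotated 5' end. A 5' end was called CpG-rich when a window of 500 bp within 500 bp of it, moved in steps of 50 bp, had an observed-to-expected CpG ratio of at least 0.6 and a GC content of at least 55%. For domains, peaks separated by at most 1000 bp were joined, and joined peaks that held a protein-coding 5' end were counted once each. In the replicated list 1327 domains held 5' ends of 2 or more genes, so a peak at a marked gene may belong to a neighbour. The CpG number of a domain was the highest count within 1000 bp of any protein-coding 5' end in it.

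The 18 gene lists, 15 of gene symbols and 3 of gene families by name pattern, were fixed before the data were examined. They cover telencephalon patterning, neural progenitors, the glutamatergic and GABAergic lineages, pan-neuronal genes, factors of the midbrain, hindbrain and spinal cord, Hox, glial, microglia and macrophage, endothelial and mural, erythroid, liver, muscle, germline and early embryo, housekeeping, olfactory receptor, vomeronasal receptor and clustered protocadherin genes. Of 359 listed symbols, 358 matched a gene and Ahsp did not. Shares were compared by Fisher's exact test (two-sided) and domain widths by a permutation test of the list's median against 100000 random sets of as many domains. Both were adjusted by the Benjamini-Hochberg method, over 18 lists for shares and over the 13 lists with at least 5 domains for widths, at a threshold of 0.05. Intervals of shares are 95% exact binomial intervals, those of odds ratios use the normal approximation on the log scale, and both cover counting error only. Genes were named by a rule fixed before the data were examined: the genes of the 20 widest promoter domains, the 3 marked members of each list with the widest domains together with its unmarked members (the leading 3 in list order where there were more than 5), and the nearest genes of the 5 distal peaks with the highest signal. Gene names outside this rule are said to be so or illustrate a list.

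On simulated peaks over 21853 genes, a planted list of 25 marked genes with 2-fold wider domains was recovered by the share test (p = 9.31e-06) and by the width test (permutation p = 0.0020). Of 200 random lists, 2% were called by the share test and 7% by the width test at an unadjusted threshold of 0.05. The alternatives were each replicate alone, the list of both replicates together, peaks with signal at or above the list's median, other overlap rules, promoter windows, joining distances, distal distances and widest shares, only the outermost 5' end of each gene, only CpG-rich genes, counting each marked gene, and random sets matched on CpG number. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.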

Results

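H3K4me3, the trimethylated form of lysine 4 of histone H3, is a chromatin mark that sits around the 5' ends of active and poised genes. It was mapped by chromatin immunoprecipitation and sequencing in mouse forebrain at embryonic day 14.5, a stage at which progenitors of the forebrain are dividing and cortical and striatal neurons are being born. There was 1 group of 2 biological replicates, each made from pooled embryos of both sexes of a B6 strain. Replicate 1 pooled 24 embryos and replicate 2 pooled 34. The deposited lists held 28794 peaks for replicate 1 and 25439 for replicate 2. A list made from both replicates together held 26565 peaks, and 21135 of these formed a list of replicated peaks. The peak lists carry no read totals, so the depth of each replicate is unknown. With 1 tissue at 1 age and no second group, the questions asked were where the mark lay, which genes carried it, and how wide it spread.

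Peaks found in both replicates were the wide, high-signal ones. Of the 28772 peaks of replicate 1 on assembled chromosomes, 22244 (77.3%) overlapped a peak of replicate 2 by at least 50% of the length of either peak, and 21490 of 25425 peaks of replicate 2 (84.5%) overlapped a peak of replicate 1. When the peaks were placed at random on their own chromosomes 100 times, the highest shares were 2.04% and 2.27%. Shared peaks had a median width of 1284 bp in replicate 1 and 1381.5 bp in replicate 2, against 226 bp and 250 bp for peaks that were not shared. Counted at full width, shared peaks held 95.1% of the length covered in replicate 1 and 96.7% of that in replicate 2. The bases covered in both replicates came to 30.8 Mb, a fraction of 0.813 of the bases covered in either. In the lowest decile of peaks by signal, 24.1% were shared in replicate 1 and 36.9% in replicate 2, and all peaks were shared from the 6th decile upwards. The shares refer to the deposited thresholds, under which 5.06% of the peaks of replicate 1 and 1.59% of those of replicate 2 had a q value above 0.05.

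**Figure D1:**
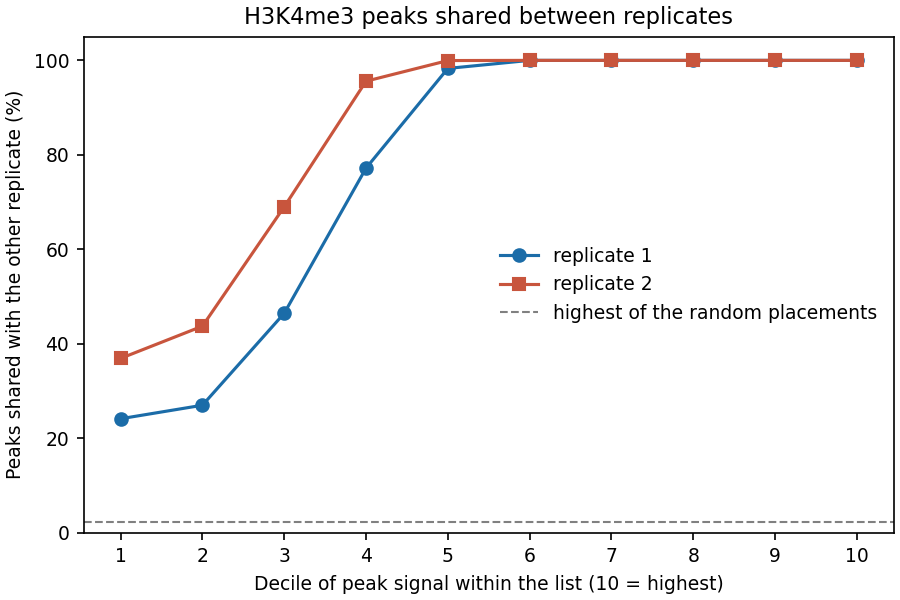
Share of H3K4me3 peaks (%, vertical axis) that overlapped a peak of the other replicate, by decile of peak signal within each replicate's own list (horizontal axis, 10 is the highest). Sharing rose from 24.1% in replicate 1 and 36.9% in replicate 2 in the lowest decile to 100% from the 6th decile, and the dashed line marks 2.27%, the highest share reached by randomly placed peaks.

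Promoters of protein-coding genes held most of the mark. In the replicated list, 67.2% of peaks came within 1000 bp of the 5' end of a protein-coding transcript. Of randomly placed peaks, 4.68% did so on average and 5.04% at most. Counted at full width, including bases further than 1000 bp from a 5' end, these promoter peaks of the replicated list held 82.9% of the covered bases. Promoters of other transcripts, such as long non-coding RNAs, held 7.60% of peaks (random mean 6.22%). Introns held 9.03% of peaks against 31.5% at random, exons 4.50% against 9.68%, and intergenic sequence 11.6% against 47.9%. Median widths followed the same division, with 1943 bp at protein-coding promoters, 587 bp in introns and 687 bp between genes. In the 2 replicates' own lists the protein-coding promoter share was 57.7% ± 3.45 (SD, n = 2), lower than in the replicated list by more than this spread, and intronic peaks made up 15.7% ± 2.07.

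A peak lay within 1000 bp of a 5' end in 14061 of 21853 protein-coding genes (64.3%, 95% exact binomial interval 63.7 to 65.0%). The replicates gave 64.7% ± 0.155 (SD, n = 2): 14013 genes were marked in both, 141 in replicate 1 only and 93 in replicate 2 only. The mark followed the CpG content of the promoter. Of 12749 genes with a CpG-rich 5' end, 12461 (97.7%) were marked, compared with 1600 of 9104 other genes (17.6%), an odds ratio of 203 (95% interval 178 to 231). Genes on the X chromosome were marked less often than autosomal genes: 477 of 948 (50.3%) against 13580 of 20722 (65.5%), with an odds ratio of 0.533 (95% interval 0.467 to 0.607; Fisher's exact test, two-sided, p = 5.96e-21). CpG-rich 5' ends were also scarcer there, at 38.1% of X-linked and 59.8% of autosomal genes. Among CpG-rich genes alone, 348 of 361 X-linked genes (96.4%) and 97.8% of autosomal genes were marked, and the difference was not resolved (odds ratio 0.603, 95% interval 0.342 to 1.06, exact p = 0.0999). Among genes without a CpG-rich 5' end the direction turned, with 22.0% of X-linked and 17.6% of autosomal genes marked. On the Y chromosome 4 of 183 genes were marked, and these 4, Ddx3y, Eif2s3y, Kdm5d and Uty, are the broadly expressed genes of the male-specific region. They are named because the count was small, after the values were seen. For any Y-linked genes with near-identical copies, absence of a peak is uncertain, because the treatment of reads matching several places is not given. The intervals cover counting error over genes only, and genes are not replicates of the experiment.

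The forebrain's own lineage genes all carried the mark. Of the telencephalon patterning factors, transcription factors such as Foxg1, Emx2 and Lhx2 that shape the early forebrain, 20 of 20 were marked. So were 24 of 24 genes of neural progenitors, among them Sox2 and Pax6, which maintain dividing radial glia. The lists of the glutamatergic lineage (22 of 22), the GABAergic lineage (25 of 25) and pan-neuronal genes (24 of 24) were marked throughout, as were 27 of 27 housekeeping genes. Each of these shares lay above that of the other genes (64.3%; Fisher's exact test over 18 lists, Benjamini-Hochberg adjusted exact p between 2.43e-05 and 0.000346). The replicates gave the same shares for these lists, except that each marked 21 of the 22 glutamatergic genes. Neurod4, named after its values were seen, was marked in the replicated list and in neither replicate's own list. Among genes with CpG-rich 5' ends only, these lists stayed at 100% and could no longer be told from the 97.7% of such genes in general (adjusted exact p = 1 for each). Lists of these sizes could not have shown an excess over 97.7%, so this comparison does not tell whether CpG content accounts for their shares. Among peaks with a signal at or above the list's median, the telencephalon (70%), glutamatergic (68.2%) and GABAergic (52%) shares did not pass the threshold (adjusted exact p of 0.130, 0.141 and 1). These shares were compared with those of other genes under the same peaks, not with the 64.3% of the full list.

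Transcription factors of the midbrain, hindbrain and spinal cord were marked nearly as completely, at 25 of 26 (96.2% in the replicated list and in each replicate, adjusted exact p = 0.000379). Phox2b, a factor of visceral motor neurons, was the exception. Among CpG-rich genes 23 of 23 of these factors were marked, which could not be told from other such genes (adjusted exact p = 1). Nearly all CpG-rich genes were marked, so an excess could not have been shown here either. Their peaks were weak. Among peaks with a signal at or above the median of the replicated list, 2 of these 26 genes (7.69%) were marked, compared with 14 of 20 telencephalon patterning factors (70.0%; odds ratio 28.0, Fisher's exact test p = 1.85e-05, a comparison chosen after the data were seen). Hox genes, which set position along the hindbrain, cord and trunk, were marked less often than other genes in the replicated list, at 15 of 39 (38.5%, adjusted exact p = 0.00154). Marked members included Hoxa13, Hoxd8 and Hoxa4, and Hoxa2 and Hoxa3 were unmarked in both replicates. Hoxa6 was marked in replicate 1 alone. The Hox share was 51.3% ± 3.63 (SD, n = 2) in the replicates' own lists, and the difference from other genes did not pass the threshold in replicate 1 (53.8%, adjusted exact p = 0.202), in replicate 2 (48.7%, adjusted exact p = 0.0533), in both replicates together (59.0%, adjusted exact p = 0.457) or with a promoter window of 2000 bp (48.7%, adjusted exact p = 0.0510).

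Lists of microglia, liver, germline, erythroid and chemosensory receptor genes were marked less often than other genes. Of microglia and macrophage genes, 3 of 20 were marked (15%, adjusted exact p = 2.43e-05): Runx1, Irf8 and Hexb. Cx3cr1, Csf1r and Aif1, characteristic of microglia and macrophages, had no peak. Liver genes were marked in 2 of 24 cases (8.33%, adjusted exact p = 9.92e-08), Apoh and Foxa3, with no peak at Alb or Afp, which encode albumin and alpha-fetoprotein. Foxa3 had a peak near a 5' end but no domain that held one in the replicated list. Replicate 1 alone marked 4 of the liver genes (16.7%, adjusted exact p = 8.02e-06), adding Trf and Ttr, which are named after their values were seen. Germline and early embryo genes were marked in 1 of 20 cases (5%, adjusted exact p = 1.82e-07), Dazl, and not at Pou5f1 or Nanog. Replicate 2 alone marked 3 of them (15%, adjusted exact p = 2.56e-05), adding Dppa3 and Tdgf1, which are named after their values were seen. Erythroid genes were marked in 6 of 19 cases (31.6%, adjusted exact p = 0.00764). These were Tfrc, the transferrin receptor gene, Sptb, Epor, Gypa, Klf1 and Nfe2, all marked in both replicates too. Gypa, Klf1 and Nfe2 are named after their values were seen. The alpha-like globin genes Hba-a1, Hba-a2 and Hba-x were not marked. Olfactory receptor genes (3 of 1092, 0.275%) and vomeronasal receptor genes (1 of 327, 0.306%, adjusted exact p = 2.21e-145) were almost bare, with odds ratios of 0.00131 and 0.00163. Most genes of these lists lack CpG-rich 5' ends. Among CpG-rich genes only, 3 of 3 microglia and 3 of 3 erythroid genes were marked (adjusted exact p = 1 for each) and 2 of 3 liver genes (66.7%, adjusted exact p = 0.239), whereas 1 of 7 germline genes was (14.3%, adjusted exact p = 7.80e-09). The receptor lists held 1 such gene each, marked in the vomeronasal and unmarked in the olfactory list. In families of near-identical copies such as these receptors and the alpha globins, absence of a peak is uncertain, because the treatment of reads matching several places is not given in the sources used here.

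The remaining 4 lists had marked shares between 40.4% and 65%. Endothelial and mural genes were marked in 13 of 22 cases (59.1%, adjusted exact p = 0.697), with peaks at Esam, Foxc1 and Mfsd2a and none at Pecam1, Cdh5 or Tek. Glial genes were marked in 13 of 20 cases (65.0%, adjusted exact p = 1). Olig2, Sox8 and Pdgfra, which act in oligodendrocyte precursors, were marked, as were Mbp, Cnp and Myrf of the myelin-forming lineage and the astrocyte genes Slc1a2, Gja1 and Aldoc. Aldh1l1 was marked in the replicated list and in replicate 1 but not in replicate 2. Unmarked genes were Gfap, Aqp4 and S100b, which mark astrocytes, and the myelin genes Mag, Mog, Mobp and Plp1. The genes beyond the leading members of the list were added after their values were seen. Skeletal and cardiac muscle genes were marked in 12 of 26 cases (46.2%, adjusted exact p = 0.0726), including Mef2c, which is also a member of the glutamatergic list, but not at Myog, Myf5 or Acta1. Among peaks with a signal at or above the list's median, endothelial and mural (9.09%), glial (25%) and muscle genes (7.69%) were marked less often than other genes (adjusted exact p of 9.72e-05, 0.0317 and 1.26e-05). Muscle genes also passed the threshold with a 500 bp window (42.3%, adjusted exact p = 0.0285) and with the outermost 5' end only (38.5%, adjusted exact p = 0.0273), and among CpG-rich genes 10 of 10 were marked. Clustered protocadherin genes, which encode neuronal adhesion proteins, were marked in 23 of 57 cases (40.4%, adjusted exact p = 0.000379), but in the list of both replicates together the share was 54.4% and did not differ from other genes (adjusted exact p = 0.123).

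**Figure D2:**
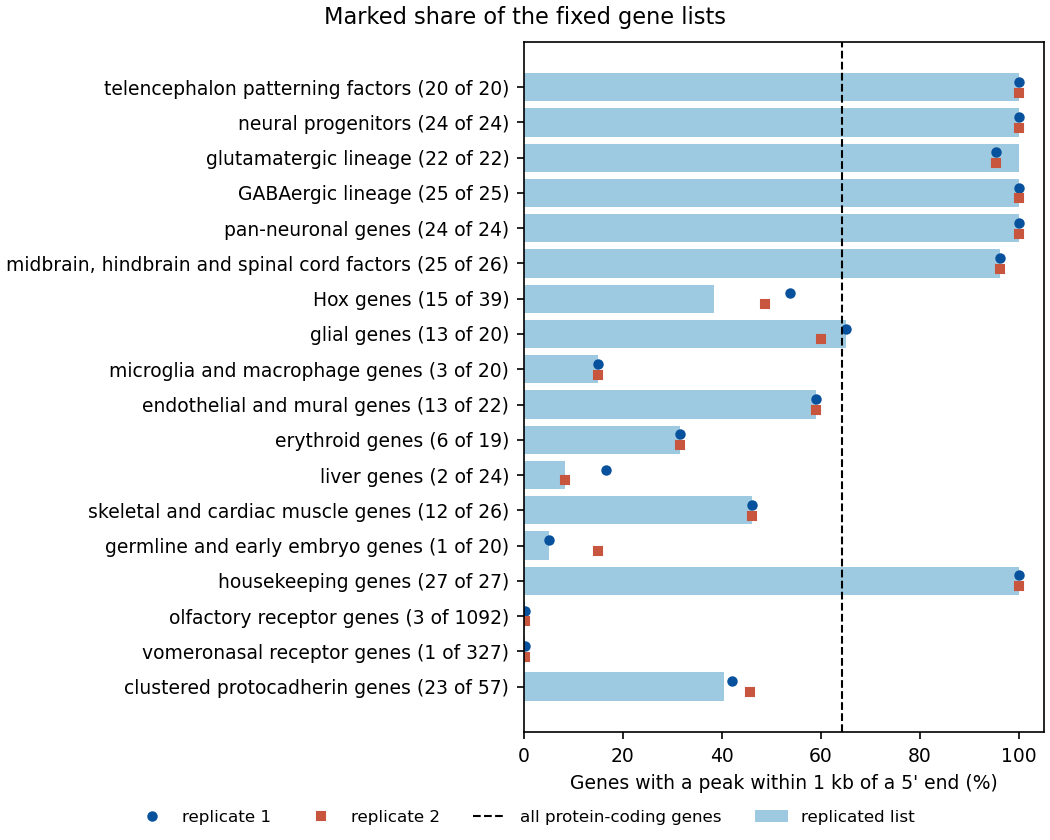
Share of genes in each fixed list with an H3K4me3 peak within 1000 bp of a 5' end (%, horizontal axis). Bars give the replicated list, circles replicate 1, squares replicate 2, and the dashed line all protein-coding genes (64.3%). Lists of forebrain lineages and housekeeping genes reach 100%, and the olfactory and vomeronasal receptor lists stay at 0.275% and 0.306%.

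Lists of forebrain lineage genes had wider domains than random sets of marked promoters. Peaks no more than 1000 bp apart were joined, which gave 13212 domains holding a protein-coding 5' end, with a median width of 2068 bp. Domains of telencephalon patterning factors had a median of 9527 bp, 4.60 times the 2069 bp of random sets of as many domains. The GABAergic lineage reached 6209 bp, the glutamatergic lineage 5598 bp, neural progenitors 5502.5 bp and pan-neuronal genes 3727 bp. The widest pan-neuronal domains were at Myt1l (13023 bp), a neuronal transcription factor gene, Tubb3 (7855 bp), which encodes a neuronal tubulin, and Elavl2 (7319 bp). All 5 lists lay above 100000 random sets (permutation test, two-sided, p = 2e-05, the smallest it can give; adjusted p = 4.33e-05 over 13 lists). Medians in the replicates' own lists were 8831 ± 617 bp for the telencephalon factors, 6591 ± 62.2 bp for the GABAergic, 5756 ± 268 bp for the glutamatergic, 5393 ± 18.7 bp for the progenitor and 3661 ± 279 bp for the pan-neuronal list (SD, n = 2). The calls of these 5 lists held in each replicate alone and under each alternative tried.

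Housekeeping genes, all of them marked, had a median of 3063 bp (adjusted permutation p = 0.00039), which was no longer above random sets when peaks were not joined (2210.5 bp, adjusted permutation p = 0.395) or among peaks at or above the median signal (2338 bp, adjusted permutation p = 0.587). Their widest domains, at Chmp2a (5524 bp), Polr2a (5066 bp) and Ywhaz (4806 bp), stayed below the median of the telencephalon factors. Factors of the midbrain, hindbrain and spinal cord had a median of 2196 bp, which did not differ from random sets (adjusted permutation p = 0.666). This depended on the setting: with gaps of up to 3000 bp joined the median was 3657 bp, above random sets (adjusted permutation p = 7.43e-05), and against sets matched on CpG number 2196 bp lay below them (adjusted permutation p = 0.0114). The widest were at Gbx2 (6376 bp), a factor of the anterior hindbrain, Mafb (5812 bp), which is also in the GABAergic list, and Egr2 (4185 bp). The difference between telencephalon factors and these factors was itself resolved, at 9527 bp over 21 domains against 2196 bp over 22 (permutation of the 2 lists' labels, chosen after the data were seen, p = 1e-05, the smallest it can give). Domains of Hox genes were narrow, with a median of 1037 bp over 13 domains (adjusted permutation p = 7.43e-05) and a widest domain of 1455 bp at Hoxa13. Clustered protocadherin genes had a median of 987 bp (adjusted permutation p = 4.33e-05), although Pcdhgc3 lay in a domain of 5096 bp. In replicate 1 alone the protocadherin median of 1338 bp narrowly missed the threshold (adjusted permutation p = 0.0504). Muscle genes had narrower domains than random sets in the replicated list (1418 bp, adjusted permutation p = 0.0366) but not in replicate 1 alone (2060.5 bp, adjusted permutation p = 0.816). Medians of glial (2475 bp), endothelial and mural (2064 bp) and erythroid genes (1770 bp) did not differ from random sets (adjusted permutation p of 0.366, 0.977 and 0.606). With gaps of up to 3000 bp joined, the glial median was 4184 bp and passed the threshold (adjusted permutation p = 0.00187). Lists with fewer than 5 domains were not tested: the microglia, liver, germline, olfactory and vomeronasal receptor lists held 3, 1, 1, 2 and 1.

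**Figure D3:**
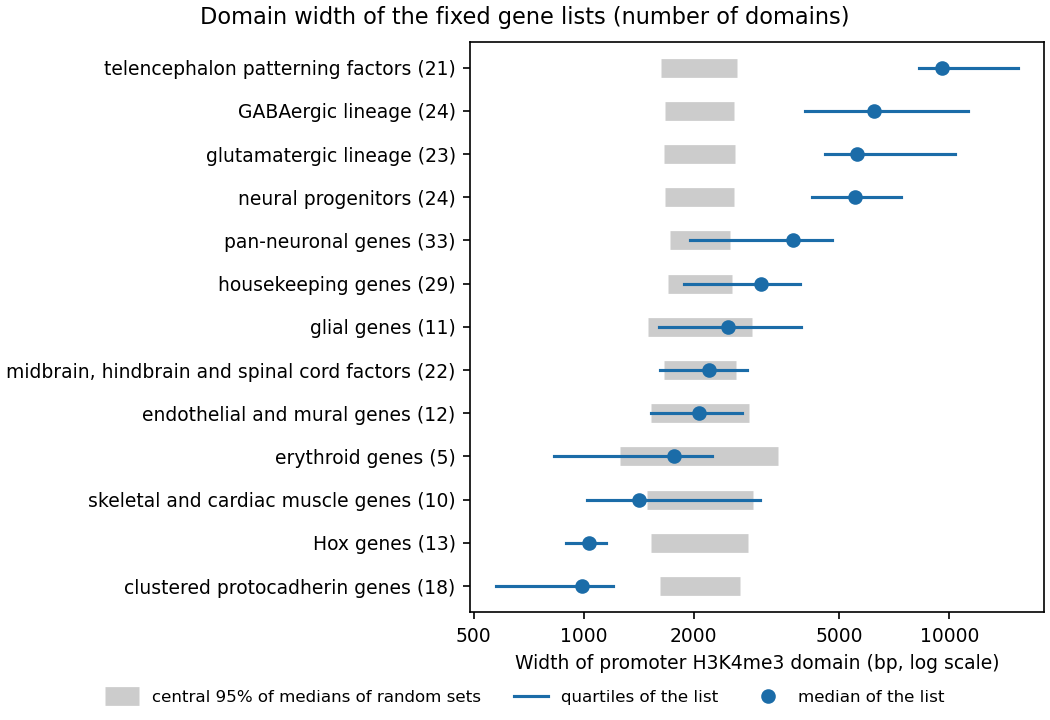
Width of promoter H3K4me3 domains (bp, log scale, horizontal axis) for each fixed list with at least 5 domains, the number of domains being given in brackets. Points are medians, lines run between quartiles, and grey bars span the central 95% of medians of random sets of as many domains. The 4 forebrain lineage lists sit at medians of 5502.5 to 9527 bp, above their grey bars, as do pan-neuronal (3727 bp) and housekeeping genes (3063 bp). Hox, clustered protocadherin and muscle genes lie below theirs.

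Among the widest 5% of promoter domains, 661 domains of at least 4762 bp, the forebrain lists were over-represented (Fisher's exact test). They took in 19 of 21 domains of telencephalon factors (90.5%, adjusted exact p = 3.74e-22), 16 of 23 of the glutamatergic lineage (69.6%, adjusted p = 1.48e-15), 16 of 24 of the GABAergic lineage (66.7%, adjusted p = 2.83e-15), 15 of 24 of neural progenitors (62.5%, adjusted p = 7.37e-14) and 9 of 33 of pan-neuronal genes (27.3%, adjusted p = 6.31e-05). Midbrain, hindbrain and spinal cord factors had 2 of 22 domains there (9.09%, adjusted exact p = 0.561; 16.7% in replicate 1 alone, adjusted exact p = 0.0509) and housekeeping genes 3 of 29 (10.3%, adjusted exact p = 0.380). The housekeeping share was 18.5% in replicate 1 alone and 17.9% in replicate 2 alone, and passed the threshold in each (adjusted exact p of 0.0199 and 0.0252), as it did among the widest 10% (27.6%, adjusted exact p = 0.0135). With gaps of up to 3000 bp joined, the midbrain, hindbrain and spinal cord factors (18.2%) and endothelial and mural genes (27.3%) passed it too (adjusted exact p of 0.0411 and 0.0330). Glial, muscle and protocadherin genes had 1 domain each, and Hox, endothelial and mural, and erythroid genes had 0.

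The 20 widest promoter domains ran from 14284 to 32936 bp, and 16 of them held a gene of a fixed list. The widest covered Dlx5 and Dlx6, homeobox genes of GABAergic neurons, on chromosome 6 from 6850005 to 6882940 (GRCm38). It joined 9 peaks over both gene bodies, the space between them, part of the non-coding gene Dlx6os1 and all of Dlx6os2. In replicate 1 this domain measured 33111 bp, and in replicate 2 it fell into 2 domains, the wider of 21547 bp. The domain of Pou3f3, a factor of upper-layer cortical neurons, spanned 31601 bp on chromosome 1 from 42683353 to 42714953 (33192 ± 2220 bp, SD, n = 2). Foxg1, required for growth of the telencephalon, lay with the predicted gene Gm43517 in a domain of 29898 bp on chromosome 12 from 49373529 to 49403426 (29675.5 ± 37.5 bp). The next were Nr2f2 (25300 bp), Meis2 (24185 bp), Lhx2 (23838 bp), the pair Dlx1 and Dlx2 (23654 bp), and Nfib (22942 bp). Domains at Sox2 (18186 bp), Nr2f1 (17553 bp), Pax6 (17162 bp), Otx1 (16321 bp), Pou3f2 (15499 bp), Arx (15371 bp), Six3 (14735 bp) and Emx2 (14284 bp) completed those of listed genes. The 4 domains without a listed gene belonged to Mn1 (20058 bp), the ephrin receptor gene Epha4 (16020 bp), Zeb2 (14872 bp), a factor of migrating cortical interneurons, and the neighbours Zic1 and Zic4 (14501 bp). Besides the Dlx5 and Dlx6 domain, Epha4 measured 7448 bp in replicate 1 and 15531 bp in replicate 2, and Nr2f1 measured 17600 and 25216 bp. Pax6 measured 22566 bp in replicate 1 and 17243 bp in replicate 2. Zeb2 measured 14613 bp in replicate 2 and fell into 2 domains in replicate 1, the wider of 10811 bp. At Six3 the widest domain was 7443 bp in replicate 1 and 7059 bp in replicate 2, because the domain fell into 2 in each.

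**Figure D4:**
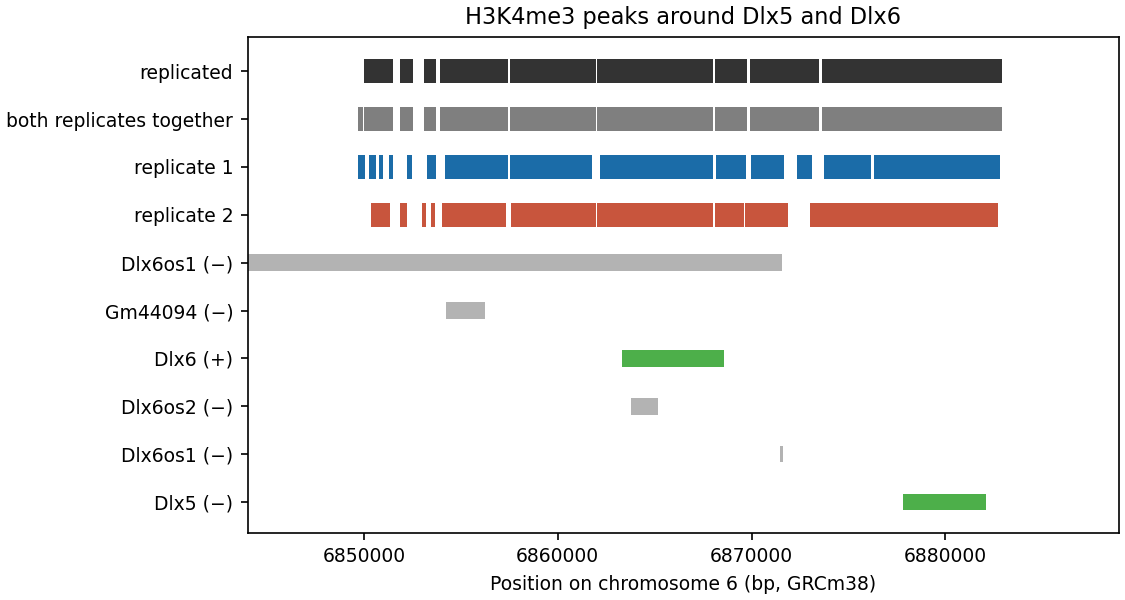
Map of the widest promoter domain on chromosome 6 (position in bp, GRCm38, horizontal axis). Blocks in the upper 4 tracks are the H3K4me3 peaks of each list, and the lower tracks are annotated genes with their strand, protein-coding genes in green and other genes in grey. Within the domain from 6850005 to 6882940, the replicated list has 9 peaks, replicate 1 has 14 and replicate 2 has 10.

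Peaks far from any annotated 5' end were few and narrow. Over 5000 bp from every annotated 5' end lay 3098 of 21123 replicated peaks (14.7%), against 72.9% of randomly placed peaks (range 72.1 to 73.5%). Their median width was 675 bp and the median of the other peaks 1723 bp, and they overlapped a peak in both replicates in 90.5% of cases, compared with 97.2% for the rest. The number depended on the list: replicate 1 alone held 4844 such peaks and the list of both replicates together 4739, whereas 137 of the replicated peaks with a signal at or above the median were distal. The distal peak with the highest signal (71.5 on the scale of the authors' peak caller) was 5926 bp wide, on chromosome 15 from 85669077 to 85675002, in an intron of the non-coding gene Lncppara and 15461 bp from its nearest 5' end. The next lay in intergenic sequence on chromosome 1, 11276 bp from Gpr161 (165280899 to 165284513, signal 60.3) and 9682 bp from the small nuclear RNA gene Gm26110 (171037647 to 171039244, signal 59.6). The remaining 2 of the leading 5 were intronic, in Macrod1 on chromosome 19 from 7164106 to 7166586 (nearest 5' end Otub1, 33878 bp away) and in Ldb3 on chromosome 14 from 34548187 to 34549807 (nearest 5' end 9230112D13Rik, 25386 bp away).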

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

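The tests of peak joining, of the strictness of the replicated list and of Hox position, and the comparison of X-linked genes without families with all autosomal genes, were chosen after the values they measure had been seen; the other tests here were fixed beforehand. No biological explanation was tested, since the design has 1 group.

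Peaks of 2 kinds entered none of the main results. The replicated list held 12 peaks on unplaced scaffolds. They lay on 6 scaffolds, with a median width of 740.5 bp and signals between 1.69 and 48.4. In the list of both replicates together, 1883 peaks (7.09%) had no matching peak in either replicate and were not in the replicated list. The list of both replicates together served only as an alternative to the replicated list. Their median width was 233 bp, their median signal was 2.76, and 16.8% lay at protein-coding promoters.

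The wide domains of forebrain lineage genes were weighed against 3 technical explanations, over the 92 domains of the union of the telencephalon, progenitor, glutamatergic and GABAergic lists (median 6347.5 bp). Random sets matched on CpG number in 20 bins had a median of 2475 bp, against 2070 bp for unmatched sets, and the union stayed 2.56 times wider, above the matched range of 2263.5 to 2729.5 bp. Matching on the highest signal in the domain left it 3.25 times wider (matched median 1952.5 bp). Without joining peaks, the ratio to random sets was 2.48. These values argue against CpG number within 1000 bp of the 5' end, peak strength and joining as the whole cause. CpG content in the rest of a wide domain was not matched, so its part stays open. A link to the lineage of the cells remains a hypothesis found on the same data.

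CpG-rich Hox genes were marked less often than other CpG-rich genes, 14 of 32 (43.8%) against 97.9% in the replicated list. Counting a peak in any of the 4 lists raised the Hox share to 68.75%, which was still below the 98.2% of other CpG-rich genes (Fisher's exact test, p = 2.08e-10), so the strictness of the replicated list may account for part of the difference but not all of it. For the whole list of 39 genes, the share in any of the 4 lists was 64.1%, close to the 65.4% of all genes. Hindbrain or spinal cord cells in the dissected tissue would add marked Hox genes, not remove them, so the comparison of paralog groups 1 to 4 with groups 9 to 13 over all Hox genes (odds ratio 0.918) does not bear on the lower share. What lies behind the rest of the difference stays open.

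The lower marked share of X-linked genes was set against promoter content and gene families. Within strata of CpG-rich and other genes the common odds ratio was 1.22 (Mantel-Haenszel, 95% interval 1.00 to 1.48), outside both outcomes written beforehand, an interval that held 1 or lay below it. X-linked genes were marked in 96.4% against 97.8% of CpG-rich genes and in 22.0% against 17.6% of other genes, so the common value joins strata that go opposite ways. With the strata joined, no lower odds for X-linked genes were left. The common value does not measure how much of the overall difference fewer CpG-rich 5' ends account for. Families were defined by gene symbol alone, as genes whose symbols match once the numbered ending is removed. Members of such a family need not share sequence. Leaving out 24 families with 5 or more X-linked members (343 X-linked genes) gave an odds ratio of 0.787 (95% interval 0.662 to 0.936), closer to 1 than 0.533 but still below it. This was the outcome written beforehand as speaking against these families as the whole cause. That outcome was a poor guide, because 3584 autosomal genes of the same families were left out too: shares rose from 50.3 to 67.1% for X-linked and from 65.5 to 72.2% for autosomal genes. Against all autosomal genes the odds ratio was 1.07 (95% interval 0.903 to 1.27), so the part these families play stays open.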

How the results depend on the processing

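The direct comparison of telencephalon with midbrain, hindbrain and spinal cord factors and the recounts of the 20 widest domains were chosen after the data were seen; all other alternatives were planned. Over 52 results, 395 alternative values were computed: 315 kept direction and side of the threshold or stayed within the replicate spread, 39 changed direction, 20 lost and 10 gained a call, and 11 moved beyond the spread or by over 1.5 times. The cause was not tested for any of these unless stated. Width and widest-share calls of the telencephalon, progenitor, glutamatergic, GABAergic and pan-neuronal lists held throughout, with medians down to 6928.5, 4702, 3852.5, 5278.5 and 3464 bp. The telencephalon median stayed 3.35 to 5.22 times that of the other regions' factors. No value was possible among peaks at or above the median signal, where those factors kept fewer than 5 domains. The shares of X-linked and CpG-rich genes and the number of marked genes kept their calls or size. No paired analysis was possible because there is only 1 group. Shared peaks need both replicates, so neither could be left out there. Read depth is unknown, and a weak or narrow peak may be missed in a shallower library.

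With each replicate alone, the ranges were 48.7 to 53.8% marked for Hox genes and 60 to 65% for glial, 5 to 15% for germline and 8.33 to 16.7% for liver genes; widths of 849 to 1338 bp for protocadherin, 1830 to 2424.5 bp for endothelial and 947 to 2060.5 bp for muscle genes; widest-domain shares of 0 to 5.88% for protocadherin, 0 to 8.33% for endothelial, 17.9 to 18.5% for housekeeping 0 to 10% for muscle, 9.09 to 18.2% for glial genes and 9.09 to 16.7% for midbrain, hindbrain and spinal cord factors; 3967 to 4844 distal peaks; and 55.3 to 60.2% of peaks at protein-coding promoters. With both replicates together, 56.9% of peaks lay at such promoters and 4739 were distal. Marked shares were then 59.0% for Hox, 54.4% for protocadherin, 68.2% for endothelial and 65% for glial genes, and the Hox and protocadherin calls were lost. The endothelial median was 2384 bp, and widest-domain shares were 4.55% for protocadherin and 7.69% for endothelial genes.

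Among peaks at or above the median signal, 95.3% lay at protein-coding promoters, 137 were distal and 100% were shared in each replicate. Marked shares fell to 52% for GABAergic, 68.2% for glutamatergic and 70% for telencephalon genes, without a call, and to 7.69% for midbrain, hindbrain and spinal cord factors, below other genes (adjusted exact p = 1.26e-05). They were 9.09% for endothelial, 25% for glial and 7.69% for muscle genes. The housekeeping median was 2338 bp, without a call, and widest-domain shares were 4% for housekeeping and 0% for glial genes. Requiring an overlap of 50% of both peaks left 67.5% of replicate 1 and 76.4% of replicate 2 shared.

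Among CpG-rich genes only, where fewer genes were tested, 100% were marked of the GABAergic, glutamatergic, progenitor, pan-neuronal, telencephalon, housekeeping, midbrain, hindbrain and spinal cord, endothelial, muscle, erythroid, microglia and vomeronasal lists, the last 3 with 3, 3 and 1 genes. Nearly all CpG-rich genes were marked, so a list at 100% could not show an excess over the others. Glial genes reached 90%, liver genes 66.7% of 3, and olfactory receptor genes 0% of 1. Glial genes were marked in 60% with a 500 bp window, 65% with 2000 bp and 60% with the outermost 5' end only. Hox genes reached 48.7% with 2000 bp. Muscle genes passed the threshold at 42.3% with 500 bp and 38.5% with the outermost 5' end.

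Without joining peaks, the housekeeping median was 2210.5 bp, and widest-domain shares were 0% for the other regions' factors and for muscle genes. With gaps of up to 3000 bp joined, medians were 4184 bp for glial, 3657 bp for midbrain, hindbrain and spinal cord and 2361 bp for endothelial genes, and widest-domain shares were 27.3% for endothelial genes (adjusted exact p = 0.0330), 18.2% for the other regions' factors, and 0% for protocadherin and muscle genes. Against sets matched on CpG number, the 2196 bp of the midbrain, hindbrain and spinal cord factors lay below random (adjusted permutation p = 0.0114) and the 2064 bp of endothelial genes turned direction. Counting each gene gave 2361 bp for endothelial genes. In the widest 2%, shares were 0% for protocadherin, glial, housekeeping and muscle genes. In the widest 10%, they were 5.56% for protocadherin, 27.6% for housekeeping (a call gained, adjusted exact p = 0.0135) and 10% for muscle genes.

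Of the 20 widest domains, 19 were among the 20 widest in replicate 2 alone, 17 in replicate 1 alone, 17 in both replicates together, 13 among peaks at or above the median signal, 12 without joining and 15 with gaps of up to 3000 bp joined.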

Other observations

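The counts by gene cluster, the comparison of unmarked CpG-rich genes and the test of the downstream share of width were chosen after the data were seen. The test of downstream reach was fixed beforehand.

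The mark was split unevenly within gene clusters. Of the 21 genes of the gamma protocadherin cluster on chromosome 18, 19 were marked (90.5%), compared with 3 of 14 in the alpha cluster (21.4%) and 1 of 22 in the beta cluster (4.55%). The 3 marked alpha genes were Pcdha12, Pcdhac1 and Pcdhac2, and the beta gene was Pcdhb19. Each replicate alone marked 19 gamma and 4 alpha genes, and 1 or 3 beta genes. CpG-rich 5' ends were found in 13 gamma, 10 alpha and 1 beta gene. In the replicated list, Hoxd had 6 of 9 genes marked and Hoxa 6 of 11, whereas Hoxb had 1 of 10 (Hoxb4) and Hoxc 2 of 9 (Hoxc10 and Hoxc13). The Hoxb and Hoxc counts moved between lists: replicate 1 alone marked 2 Hoxb and 5 Hoxc genes, and replicate 2 alone 4 Hoxb genes and 1 Hoxc gene. For Hoxa the counts were 7 and 6, and for Hoxd 7 and 8. Differences between clusters were not tested.

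Of the 12749 genes with a CpG-rich 5' end, 288 (2.26%) had no peak in the replicated list, and 3 fixed lists held more of them than other genes did (Fisher's exact test, Benjamini-Hochberg over 13 lists). Germline genes were unmarked in 6 of 7 cases (85.7%, adjusted exact p = 5.64e-09): Ddx4, Mael, Stra8, Sycp1, Sycp3 and Tex101, several of which act in meiosis. These 6 were unmarked in both replicates too. Hox genes were unmarked in 18 of 32 cases (56.2%, adjusted exact p = 6.37e-21) and clustered protocadherin genes in 9 of 24 (37.5%, adjusted exact p = 5.69e-09). Counting a peak in any of the 4 lists, 22 of the 32 Hox genes were marked (68.75%). Of the 9 protocadherin genes, Pcdha11 was marked in replicate 2. Their peaks in the list of both replicates together were not counted here. By contrast, the 23 CpG-rich factors of the midbrain, hindbrain and spinal cord and the 10 CpG-rich muscle genes all had a peak in the replicated list. Gfap was the only unmarked gene among 10 CpG-rich glial genes.

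A hypothesis was that the widest 5% of promoter domains extend into the gene more than other domains do. It was tested on domains of a single gene whose 5' ends lay within 200 bp. Of 311 such wide domains, 279 reached further downstream than upstream (89.7%), against 90.3% of 8590 others (Fisher's exact test, p = 0.697), so the direction of the longer arm did not separate them. A share no higher than among the others was the outcome written beforehand as speaking against the hypothesis. The share of the width that lay downstream did separate the wide domains: its median was 76.1% in them and 68.7% in the others, above the 67.1 to 70.8% of random sets of as many domains (permutation p = 2e-05, the smallest it can give). Median arms were 4444 bp downstream and 1436 bp upstream in the wide domains, and 1227 bp and 561 bp in the others. The second test was chosen after the data were seen, so an extension that is mainly downstream remains a hypothesis only.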
